A study of Mus musculus with 42 samples.

How the data were processed

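Kidney RNA of 42 mice was sequenced as paired-end reads of 150 bases, per the labels' protocols. The aligner, counting tool, genome build, annotation and normalization were not given in the sources used here. The authors deposited 2 tables, 1 per diet, each with 56691 genes and 7 columns of expression. The headers name the treated table by another abbreviation than EpSA, and it was matched through the file named in the descriptions of the EpSA samples. The deposited expression values are taken as FPKM, a unit the headers do not name: they are not whole, their sums differ between columns, and the lowest nonzero value falls with gene length. In all values the last decimal, in thousandths, is 0, 3 or 7, as in means of 3 values rounded to hundredths, so each column is read as the authors' mean over the 3 mice listed for that diet and time. The tables also hold deposited p-values and q-values of rhythm from ARS, JTK, Lomb-Scargle and their combination meta2d, per the file headers, with phases and periods in hours, other amplitudes on the scale of expression, and a deposited ratio of amplitude to baseline. The statistics are taken as computed per diet on the 7 means that stand beside them, which the headers do not state. Version and settings were not given in the sources used here. Depth is unknown, so no counting error can be given.

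The tests fixed before the data were examined had assumed values per library or statistics alone, and the tables hold means per time. The models for libraries were therefore fitted to the 14 means, with each mean taken as 1 sample, a choice made after the tables were seen. The error in every test is then the spread between times that the model leaves, not the spread between mice. Genes with a mean of at least 1 FPKM (13344) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a pseudocount of 1, and fold changes on that scale understate those of low genes. The diet model had time as a factor and 6 residual degrees of freedom. Rhythm within a diet was a 24 h cosine and sine with 4, and the difference of rhythm was their interaction with diet with 8. P-values were adjusted by Benjamini-Hochberg at 0.05. Of the gene identifiers, 52073 had a symbol in the reference names and 4618 had none. Gene coordinates come from a GENCODE annotation of GRCm38.

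In total 28 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and with an estimated one, and by exact sign flips of the 7 time differences. The text names every measured clock gene, the 10 lowest meta2d q per diet outside the clock list, the 10 highest and 10 lowest log2 changes among called genes, up to 4 members per list, and the 10 lowest p of the difference of rhythm. Genes known only by a model number were passed over, which left 9 lower genes. Some genes that this rule selects are not reported here. List members with an absolute log2 change under 0.2 are not named. Diets were also swapped within times in 64 ways and times reordered in 100 ways per diet. Clock readings of each pool came from cosine curves of the clock genes in chow, each chow pool being read from curves fitted without it.

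The diet and rhythm models were tested on simulated data with the real gene means. The spreads were those left by the diet model, drawn independently for each gene. For the diet difference over 13344 genes, 40 of 50 genes changed by 0.5 on the log2 scale were recovered and 50 of 50 changed by 1, with 8 false calls. For the cosine, 31 of 50 genes of amplitude 0.5 and 49 of 50 of amplitude 1 were recovered, and for the difference of rhythm 25 and 49 of 50. In the data the rhythm fits also carry variation between times that the diet model removes. Their recovery here is thus for an easier setting. A simulated clock shift of -2 h was read as -1.98 h. That simulation used exact cosine curves with independent noise of a set size, not the real spreads. It therefore does not show the error of the shift in the data. Alternatives covered the pseudocount, the filter, the scaling, the rhythm statistic and single times left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other steps.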

Results

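The series measured gene expression in the kidneys of male C57BL/6 mice by RNA sequencing, to ask how the time of day and a diet with EpSA (epoxystearic acid, an oxidised fatty acid of heated oil) relate in the kidney. Mice were 6 weeks old at the start and ate either a standard chow or a high-fat diet with 3% EpSA for 14 weeks, under 12 h of light and 12 h of dark. Kidneys were taken at zeitgeber times (ZT, hours after lights on) 1, 5, 9, 13, 17, 21 and 25, with 3 mice listed per diet and time, 42 libraries in all. The deposited values are 14 means in FPKM, 1 per diet and time, called pools here, so no spread between mice can be given and the depth of the libraries is unknown. The pools held between 27796 and 29783 genes above 0, and their FPKM summed to between 400590 and 435621. A high-fat diet without EpSA was not analysed here, so fat and EpSA cannot be separated in any difference below.

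Rhythms within each diet were examined to ask which genes cycle over the day. Several circadian clock genes oscillated strongly in chow kidneys. Dbp, an output activator of the clock, ranged from 1.21 FPKM at ZT 1 to 32.04 at ZT 13, and Arntl, which encodes the activator BMAL1, from 0.35 at ZT 13 to 4.68 at ZT 1. In EpSA kidneys Dbp was highest at ZT 9, at 38.93 FPKM, and Arntl at ZT 21, at 3.25. A 24 h cosine fitted to log2(FPKM + 1) gave Dbp an amplitude of 2.00 ± 0.15 (SE) in chow and 2.00 ± 0.09 in EpSA. Of the 18 clock genes tested, 7 passed the cosine test in chow and 2 in EpSA over all 13344 genes tested, and 17 and 12 did when adjusted over the list alone. Beyond the clock list, Palm3, Slc16a1 (a monocarboxylate transporter), Clpx, Dtx4, Nat8f5 and Gm43401 passed in chow, and Slc16a1, Ypel2, Tfec and Snord32a in EpSA. Clpx, Dtx4, Nat8f5, Gm43401, Ypel2 and Tfec were named after their values were seen. Snord32a had a deposited baseline of only 1.09 FPKM in chow and 1.13 in EpSA, near the floor of 1 for testing. In all, 13 genes passed in chow and 6 in EpSA, with Dbp, Arntl and Slc16a1 in both. With 1 time left out the chow count was 3 without ZT 5 and 0 without any other time, and with no filter on low values the counts were 0 in both diets. The EpSA count was 5 without ZT 5, 3 without ZT 17, 2 without ZT 1, ZT 13 or ZT 25, 1 without ZT 21 and 0 without ZT 9, and the genes in both numbered 1 without ZT 5 and 0 without any other time.

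In the authors' deposited table of rhythm statistics, no gene had a meta2d q-value under 0.05 in chow, where the lowest was 0.051 (Palm3). The authors' deposited table gave 3 such genes in EpSA, namely Maco1 at 0.045, Gm13461 at 0.045 and Gm32633 at 0.035, of which the last pair were named after their values were seen. By the JTK q-value in the authors' deposited table the count was 0 in both diets, since the lowest JTK p for 7 values was 0.0071. At an unadjusted meta2d p under 0.05, 1558 of 13255 genes with a base of at least 1 passed in chow and 1319 of 13418 in EpSA. Evenly spread p-values would give 663 and 671. Because meta2d combines ARS, JTK and Lomb-Scargle p-values of the same means, its p need not be evenly spread without a rhythm. An excess over chance can therefore not be read from these counts. Among the lowest q-values in the authors' deposited table, those after Palm3 in chow included Slc16a1, Tspan4, Ttc38, Crbn, Psmd11, Rnf138, Nfib, Zfand1 and Vps53, and those after Maco1 in EpSA included Slc29a3, Avpr1a (a vasopressin receptor), Tril, Zfp740, Snord32a, Kdm1b, Pcid2 and Anxa7. When the deposited p was adjusted only over genes with a base of at least 1, 47 genes passed in chow and 2 in EpSA.

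Genes called rhythmic were compared between the diets. No gene had a meta2d q under 0.05 in both. At an unadjusted p under 0.05, a criterion chosen after the data were seen, 240 genes were shared against 152 for independent lists (odds ratio 1.84, two-sided Fisher exact p = 5.5e-14, across genes, which are not independent replicates). Among genes passing at that criterion, the clock list held 17 of 18 members in chow (Fisher exact, adjusted p = 6.5e-14) and 14 of 18 in EpSA (adjusted p = 4.3e-10). The fibrosis and matrix list held 13 of 21 in chow (adjusted p = 8.9e-07) and the tubular injury list 6 of 13 (adjusted p = 0.02), while neither passed in EpSA. With a base of at least 5, the tubular injury list held 4 of 9 in chow and no longer passed (adjusted p = 0.099). A difference between the diets in these list counts was not tested. In chow the matrix and injury list means were highest at ZT 5 and lowest at ZT 17 (2.95 and 2.43, 3.7 and 3.32 on log2(FPKM + 1)). A list of immune cell markers had its extremes at the same times (3.42 and 2.53). Whether these calls reflect a daily rhythm or that difference between pools was not tested.

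The time of the peak differed between the diets in several clock genes. Tef peaked at 13.4 ± 0.35 h in chow and 10.7 ± 0.4 h in EpSA, Dbp at 12.1 ± 0.32 and 9.9 ± 0.17 h, Nfil3 (a repressor of clock output) at 23.4 ± 0.38 and 20.1 ± 0.43 h, and Arntl at 0.5 ± 0.4 and 22.7 ± 0.21 h (cosine fit, SE). These genes passed the limma test of the difference of rhythm when adjusted over the list alone, with an adjusted p of 0.0077 for Tef and Dbp, 0.0082 for Nfil3 and 0.032 for Arntl. Over all genes 0 passed in limma, with 585 at an unadjusted p under 0.05, fewer than the 667 expected by chance. The 10 lowest p belonged to Slc16a1, Srpx2, Tef, Glipr1, Dbp, Slc16a10, Cyp4a32, Hnf4aos, Nfil3 and Sgk1. In the deposited phases of the authors' deposited table, 15 of 18 clock genes were earlier in EpSA, with a median difference of -0.8 h. An exact sign-flip test of their mean of -0.68 h over those genes gave p = 0.26, genes not being independent replicates. Rora, later by 7.5 h and with an unadjusted meta2d p over 0.05 in both diets, sets that p: without it the mean was -1.16 h and the exact p = 0.0021, and without any other single gene p was between 0.2 and 0.44. For the 14 clock genes with an unadjusted p under 0.05 in both diets the mean was -1.34 h (exact p = 0.00061), and both of these subsets were chosen after the data were seen. The median cosine difference of -1.65 h was reached in size by 9 of 64 swaps of diets within times (exact p = 0.1406, two-sided). Without ZT 5 or without ZT 17, 0 clock genes passed the test of the difference. Among the 240 shared genes, 175 were earlier in EpSA in the authors' deposited table, with a median difference of -1.43 h and an interquartile range from -2.89 to 0.18 h. Their median log2 ratio of relative amplitude, EpSA over chow, was -0.06. For the 18 clock genes this median was -0.28 in the authors' deposited table, with 12 lower in EpSA. An exact sign-flip test of the mean log2 ratio of -0.33 over these genes gave p = 0.013, genes not being independent replicates. The median log2 ratio of their cosine amplitudes was -0.19, reached in size by 25 of 64 swaps of diets within times (exact p = 0.3906, two-sided).

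Other clock genes were Clock, Npas2, Per1, Per2, Per3, Cry1, Cry2, Nr1d1, Nr1d2, Rora, Hlf, Bhlhe40, Ciart and Bhlhe41, the last below the level for testing. Npas2 peaked at 1.4 h in chow and 23.7 h in EpSA, Ciart at 12.7 and 10.4 h, Per3 at 13.5 and 12 h, and Nr1d1 at 9.6 and 7.8 h. Per2 peaked at 15.8 and 15.9 h and Cry2 at 13.8 h in each diet. Bhlhe40 peaked later in EpSA, at 14.4 ± 0.69 h in chow and 17.9 ± 1.38 h in EpSA. Rora had a log2 amplitude of 0.1 in chow and 0.05 in EpSA. In EpSA, Per2 was at 4.31 FPKM at ZT 1 and 12.99 at ZT 25, the same clock hour a day later. In chow, Per2 was at 4.33 and 5.39 FPKM. In the reference annotation of mouse build GRCm38, which may not be the build of the authors, Dbp (ENSMUSG00000059824) lies on chromosome 7 from 45705088 to 45710203 and Tef (ENSMUSG00000022389) on chromosome 15 from 81802421 to 81826863.

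**Figure D1:**
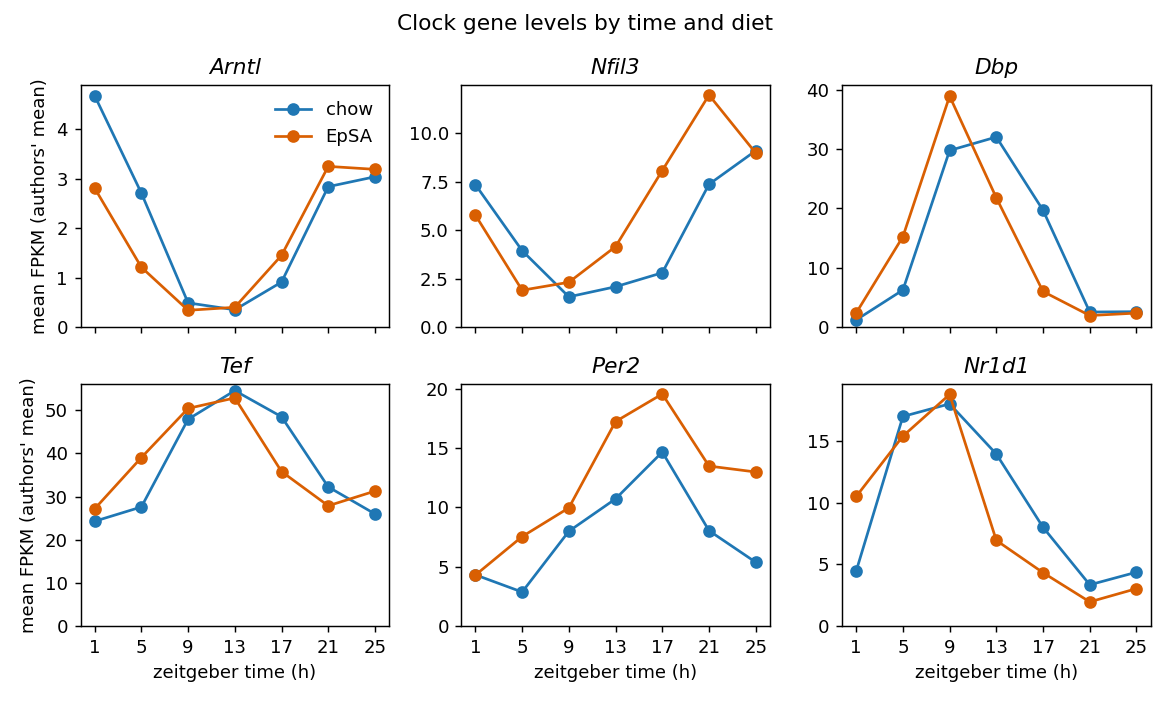
Mean FPKM (vertical axes) of 6 clock genes against zeitgeber time in hours, with 1 point per diet and time, each the authors' mean with no error given. Dbp is highest at ZT 13 in chow (32.04) and at ZT 9 in EpSA (38.93), and Per2 in EpSA is at 4.31 at ZT 1 and 12.99 at ZT 25.

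Levels averaged over the day were compared between the diets. Cpeb3, which encodes an RNA-binding regulator of translation, was higher in EpSA by 0.72 ± 0.06 on the log2(FPKM + 1) scale (SE, adjusted p = 0.011) and higher at 7 of 7 times. The mitochondrial ribosomal RNA mt-Rnr2 rose by 0.68 ± 0.09, Mir10a by 0.72 ± 0.11 and Ftcd, an enzyme of histidine breakdown, by 0.49 ± 0.08. Apoh, which encodes a plasma apolipoprotein, fell by 0.61 ± 0.09, the linker histone Hist1h1c by 0.5 ± 0.08 and Mpped1 by 0.48 ± 0.05. In limma, 23 genes were higher and 10 lower in EpSA at an adjusted p under 0.05, and 2556 had an unadjusted p under 0.05 against 667 by chance. All 33 called genes were on the same side at 7 of 7 times. Passing nearly implies this, since the error is the spread between times, so it is no further support. The other named higher genes were Rnpc3, Pnisr, Gria3, Firre, Ccnl2 and Prodh2, from 0.29 to 0.42. Rnpc3, Pnisr and Ccnl2 are tied to splicing and Firre is a nuclear RNA. Other lower genes were Smim10l2a, Tmem37, Ramp3, Tmem254a and Frzb, from -0.44 to -0.27. Reads of mt-Rnr2 and Tmem254a can be shared with near-identical copies, so their values are uncertain. The source of reads at Mir10a, the microRNA or an overlapping transcript, was not tested. With the median of all genes set to 0 the counts were 14 higher and 3 lower, and without ZT 5 or without ZT 25 they were 0 and 0. They were also 0 and 0 with no filter on low values, and 53 and 17 by quantile normalization. Leaving out any other single time left at most 6 higher and 5 lower.

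Gene lists fixed beforehand were compared between the diets with camera. The sterol and fatty acid synthesis list was lower in EpSA, with 26 of 28 members below 0, a mean log2 difference of -0.143 ± 0.035 (SE over 7 times) and lower means at 7 of 7 times (adjusted p = 0.00015, and adjusted p = 0.58 with an estimated correlation). Its members Scd1, a fatty acid desaturase, Idi1 and Mvk were at -0.39, -0.33 and -0.27. Of this list 0 genes passed over all genes and 5 were lower when adjusted over the list alone. The red blood cell list was lower, with 7 of 7 members below 0, a mean of -0.373 ± 0.077 and lower means at 7 of 7 times (adjusted p = 0.00013, and adjusted p = 0.58 with an estimated correlation), and 5 members lower when adjusted over the list alone. Hba-a2, Hba-a1, Hbb-bs and Hbb-bt, the globin genes, were at -0.88, -0.55, -0.43 and -0.32, and near-identical copies make the split between them uncertain. The mitochondrially encoded list was higher, with 13 of 13 members above 0 and a mean of 0.244 ± 0.069 (adjusted p = 2.2e-07, and adjusted p = 0.63 with an estimated correlation). Its mean difference was above 0 at 6 of 7 times, but only 0.014 at ZT 17, and was -0.008 at ZT 25. Its members mt-Nd5, mt-Atp8, mt-Nd4l and mt-Nd2 were at 0.43, 0.38, 0.38 and 0.29, and 10 were higher when adjusted over the list alone.

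The podocyte list, markers of the filtration cells of the glomerulus, was higher in 8 of 8 members with a mean of 0.195 ± 0.06 and higher means at 6 of 7 times (adjusted p = 0.00015, and adjusted p = 0.63 with an estimated correlation), and 6 were higher when adjusted over the list alone. Nphs1, Podxl and Wt1 were at 0.3, 0.22 and 0.22. The immune cell list was lower in 15 of 15 members with a mean of -0.3 ± 0.145 and lower means at 5 of 7 times (adjusted p = 0.00019, and adjusted p = 0.87 with an estimated correlation), and 2 were lower when adjusted over the list alone. Lyz2, C1qa, C1qb and C1qc, macrophage genes, were at -0.65, -0.57, -0.48 and -0.43. The mean of the immune cell list differed by -0.851 at ZT 1 and -0.613 at ZT 5, and by 0.284 at ZT 17, and the chow pools from ZT 1 to ZT 13 also held high interferon and antigen presentation genes. None of the 28 lists passed with an estimated correlation. Exact sign-flip tests over the 7 times gave p = 0.0156 for the sterol and red blood cell lists, the smallest they can give, and 0.0312 for the mitochondrial and podocyte lists, with adjusted p = 0.218 for each over the 28 lists, and 0.125 for the immune cell list (adjusted p = 0.583).

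The remaining lists did not pass camera. Oxylipin enzymes had a mean of 0.011 ± 0.024, with 1 gene higher and 1 lower when adjusted over the list alone. Cyp4a14, a fatty acid hydroxylase, was at 0.92 ± 0.27 (adjusted p = 0.14) and higher at 7 of 7 times, Ptgds at -0.39 ± 0.08 (adjusted p = 0.065), Ephx1 at 0.33 and Cyp4a12a at -0.32. In the fatty acid oxidation list the mean was 0.043 and the median -0.019, with Fabp1 at 0.34 and Acot3 at 0.33. The tubular injury list had a mean of 0.05 ± 0.121 with 0 genes passing, and its Cdkn1a was at 0.58 ± 0.32 (adjusted p = 0.35). Among hormone genes Ren1, which encodes renin, was at 0.47 ± 0.09 (adjusted p = 0.061) and Cyp27b1 at 0.47. In the loop and distal list Umod and Slc12a1, markers of the thick ascending limb, were at -0.39 and -0.32, and Slc12a3 of the distal tubule at 0.23. Slc5a12 and Slc5a2 of the proximal tubule were at 0.39 and 0.36, and Slc22a7 at -0.33. Fkbp5 and Sgk1, targets of glucocorticoids, were at -0.39 and 0.39, Il34 at -0.32, Ccn2 at 0.39, Rbm3 at 0.32, Ugt1a6a at 0.3, Jun at 0.32, Jund at -0.32, and Ucp1, a brown fat gene, at -0.82, none passing over all genes. Mean log2 differences of the other lists were -0.291 for interferon response (adjusted p = 0.068), 0.652 ± 0.636 for the 3 adrenal genes tested, which were high in the EpSA ZT 9 pool, 0.049 for ER stress, -0.033 for NRF2 targets, -0.18 ± 0.258 for fat tissue, 0.006 for the cell cycle, -0.037 for the collecting duct, 0.097 ± 0.04 for the clock (adjusted p = 0.085), 0.033 for endothelium, 0.058 for matrix, 0.036 for glucocorticoid targets, 0.013 for glucose metabolism (median -0.036), 0.06 for heat shock, 0.032 for immediate early genes, -0.101 for inflammation, 0.006 for liver and muscle, -0.066 ± 0.059 for nuclear respiratory chain genes, -0.004 for the proximal tubule, -0.024 for loop and distal tubule and 0.071 for hormones. The fat tissue mean was 0.034 without ZT 13, and the nuclear respiratory chain mean -0.011 without ZT 21. The interferon mean was -0.097 without ZT 1 and -0.151 without ZT 13, the inflammation mean -0.029 without ZT 1, and the matrix mean 0.005 without ZT 17. In all, 9 of 28 means turned sign with some single time left out, namely those of fat tissue, ER stress, the cell cycle, endothelium, glucose metabolism, liver and muscle, loop and distal tubule, the proximal tubule and tubular injury. The clock list had higher means at 6 of 7 times and 2 genes higher when adjusted over the list alone, with Per2 at 0.61 ± 0.13 (adjusted p = 0.08 over all genes), Per1 at 0.34 ± 0.08 (adjusted p = 0.096) and Per3 at 0.32 ± 0.1 (adjusted p = 0.14).

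**Figure D2:**
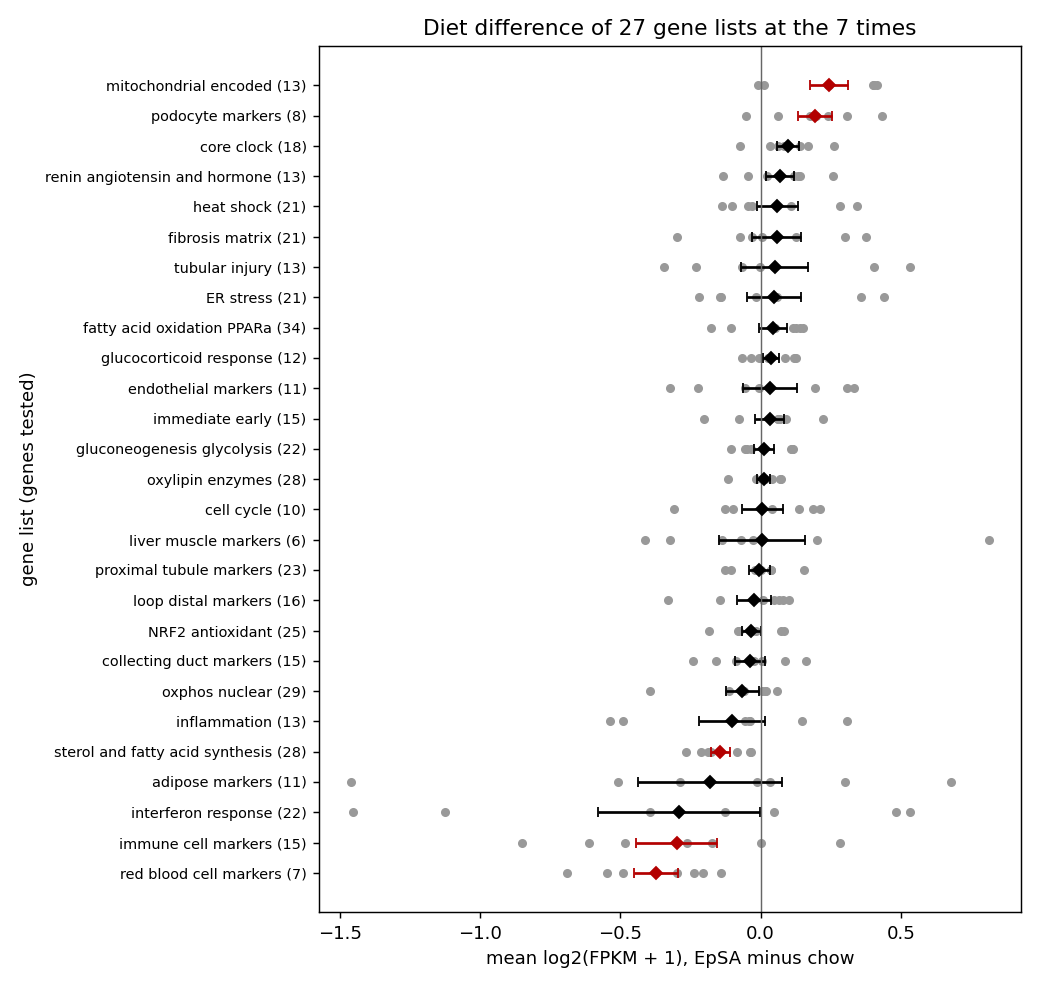
Mean log2(FPKM + 1) difference, EpSA minus chow (horizontal axis), of 27 of the gene lists; grey points are the 7 times, diamonds the mean with its SE over times, red where camera passed. The sterol and red blood cell lists lie below 0 at 7 of 7 times; the adrenal list, set by the ZT 9 pool, is not drawn.

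At single times the diets were compared by values, since 1 mean per diet and time allows no test. The interferon list, which includes antigen presentation genes, was lower in EpSA by a mean log2 difference of -1.453 at ZT 1 and -1.128 at ZT 13, and was above chow by 0.484 at ZT 17 and 0.533 at ZT 21. H2-Ab1, a class II antigen presentation gene, was at 151.23 FPKM in chow at ZT 1 and 28.46 in EpSA, and C1qa at 35.3 and 13.43. Over the day H2-Ab1, H2-K1, H2-Aa and Psmb8 were at -1.05, -0.78, -0.7 and -0.67 (adjusted p between 0.18 and 0.27 in limma). In the EpSA ZT 9 pool the adrenal genes Hsd3b1 and Cyp21a1, enzymes of steroid synthesis, were at 50.37 and 27.33 FPKM, against at most 0.16 and 0.05 in the other pools. The number of genes at least 1 apart on log2(FPKM + 1) was 140 at ZT 1, 49 at ZT 5, 61 at ZT 9, 128 at ZT 13, 66 at ZT 17, 232 at ZT 21 and 55 at ZT 25. These counts have no error. At the time of the largest count, the chow ZT 21 pool held the fewest genes above 0 of all pools (27796) and the highest FPKM sum (435621). Whether the count at ZT 21 reflects the diet or that pool was not tested.

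**Figure D3:**
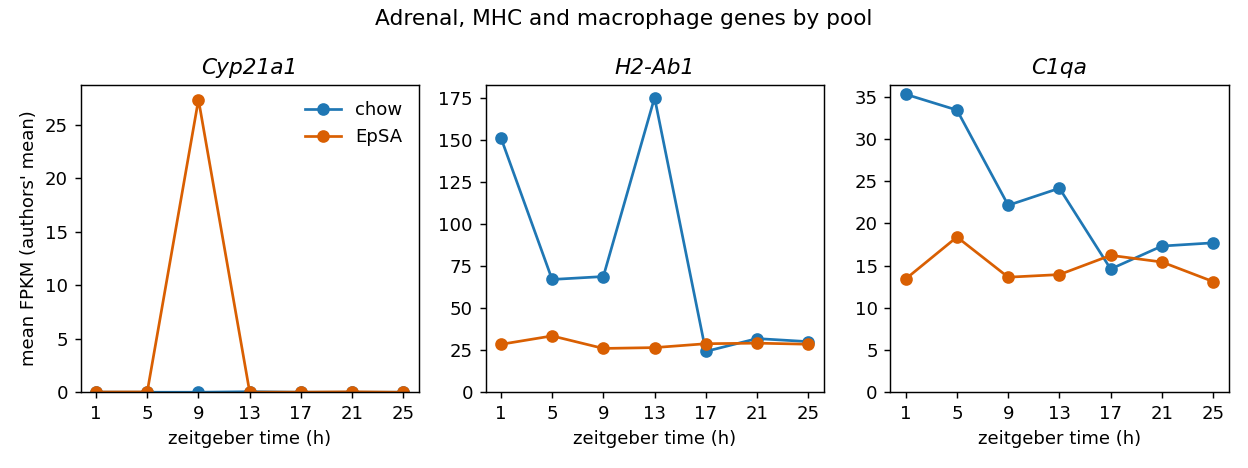
Mean FPKM (vertical axes) of Cyp21a1, H2-Ab1 and C1qa against zeitgeber time in hours, 1 point per diet and time, each the authors' mean with no error given. Cyp21a1 stands at 27.33 in the EpSA ZT 9 pool, and H2-Ab1 in chow at 151.23 at ZT 1 and 30.06 at ZT 25.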

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

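The tests of clock time and of the chow interferon genes were chosen after those results were seen, as were the comparisons with other splits. Of 62 sets of 7 pools examined, 4 held a pool far from the others, where about 3.1 are expected by chance. The adrenal list in the EpSA ZT 9 pool had a mean of 4.91 on log2(FPKM + 1), against 0.39 to 0.5 in the other EpSA pools. The nuclear respiratory chain list in the chow ZT 21 pool was at 7.65, against 7.32 to 7.45. The podocyte list in the chow ZT 5 pool was at 2.96, against 2.53 to 2.71. The loop and distal list in the EpSA ZT 1 pool was at 5.14, against 5.3 to 5.39. The rhythms of Tef, Dbp, Nfil3 and Arntl differed between the diets, with limma interaction p adjusted over the clock list alone of 0.0077, 0.0077, 0.0082 and 0.032, and none passed over all genes.

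The 33 genes called between the diets were more than any other arrangement gave. The highest of the other 63 swaps of diets within times had 1, and 1 of 64 swaps, the real one, gave as many. The swaps argue against an arbitrary grouping of the pools. They cannot exclude chance, since 64 swaps are few and the count was 0 without ZT 5 or without ZT 25. For the difference of rhythm 0 genes were called and the highest other swap gave 1. With 0 calls every swap gives at least as many. The result of 64 of 64 was therefore fixed in advance and cannot decide about chance. For the cosine in chow, 13 genes were called and 2 of 100 orders of the times, the real one included, gave as many. The highest other order gave 55, several times the real count. A wrong order of the times can thus give more calls, so chance is not excluded. Why that order gave 55 was not tested. In EpSA 6 genes were called, 1 of 100 orders, the real one, gave as many and the highest other gave 5. The real order ranked first, but the count was 0 without ZT 9, so chance is not excluded there either.

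Steroid synthesis genes stood out in the EpSA ZT 9 pool, where 10 of 10 adrenal markers were the highest of the 14 pools. A list of 8 markers of the adrenal medulla, written before their values were read, tested whether adrenal tissue was in that pool: 7 of 8 were highest there, Chga at 15.57 FPKM and Chgb at 17.8 against at most 0.06 and 0.1 elsewhere. Slc18a1, which the kidney pools held at a median of 29.85, was not. Induction of cortical steroid synthesis in kidney cells would leave medullary genes low, and the 7 argue against it. Adrenal tissue in the sample of at least 1 of the mice may explain the pattern, and no diet effect on these genes was tested beyond it.

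Clock genes in EpSA differed between ZT 1 and ZT 25: 8 of 18 were at least 0.5 apart on the log2 scale, against 1 of 18 in chow. The median absolute difference of the clock genes was less far apart between the diets, at 0.33 in EpSA and 0.24 in chow. Over all tested genes it was 0.125 and 0.118. The chow ZT 25 pool, read from curves fitted without it, also lay before its nominal time, at -2.05 h. Read from the chow curves, the EpSA ZT 25 pool was at -4.55 h from its nominal time, beyond the largest error of 2.3 h among chow pools, and at -6.62 h from the median offset of the other EpSA pools, so a wrong time for that pool may contribute. The ZT 1 pool read 3.6 h ahead, but 5 of 7 EpSA pools read ahead, ZT 13 by 2.85 h, and ZT 1 lay 1.88 h from the median of the others, within that error, so a wrong time for it cannot be told apart from the offset of the other pools. One offset common to all EpSA pools would move both alike, and their readings lay 8.15 h apart, which argues against it as the cause of this difference. A steady effect of the diet on the clock would also act alike at the same clock hour, and no other effect of the diet on this difference was tested.

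Interferon and antigen presentation genes differed between chow pools. A rhythm of the time of day would make ZT 1 and ZT 25 alike, but the list was 1.38 ± 0.09 (SE over genes) higher on the log2 scale at chow ZT 1, in 22 of 22 genes, while its SD over the 7 EpSA pools was 0.28. More immune cells of all kinds alone would raise their markers at least as much. These were higher by 0.43 ± 0.15, in 11 of 15 genes, which argues against that as the whole cause. The list averages several cell types, so an increase of a single type was not tested. The macrophage genes C1qa and Lyz2 were at 17.7 and 39.78 FPKM at chow ZT 25, and at 35.3 and 77.31 at chow ZT 1. An immune response in some chow mice, or a library batch, of which the labels name none, stays open, since neither was tested.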

How the results depend on the processing

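Single times left out (except ZT 25 for genes higher or lower, which was planned), the joint removal of ZT 1 and ZT 25, the cosine calls in place of the deposited ones, scalings and filters planned only for other results, and the unadjusted criteria were chosen after seeing the data. No paired analysis was possible because the tables hold means per time with no replicate columns to pair by number; the diets were matched by time in the diet model, sign flips and swaps. For the same reason replicates were not left out, and count tests and a variance recovered from the Lomb-Scargle p were not run. Genes rhythmic in chow numbered 0, and 47 with p adjusted over genes with a base of at least 1, 1558 at an unadjusted p and 13 by the cosine. In EpSA there were 3, and 0 by the JTK q, by the Lomb-Scargle q and at meta2d q under 0.01, 1319 at an unadjusted p and 6 by the cosine. Shared genes numbered 0, and 240 and 63 at an unadjusted p under 0.05 and 0.01, 3 by the cosine and 322 by its unadjusted p. The cosine calls in chow went from 13 to 0 with no filter, 8 with a pseudocount of 0.1, 7 at a minimum mean of 5, 6 with medians set to 0, 8 by quantile normalization, 0 to 3 with single times left out and 0 without ZT 1 and ZT 25. Those in EpSA went from 6 to 0 with no filter, 0 to 5 with single times left out and 1 without ZT 1 and ZT 25, and those in both from 3 to 0, 0 to 1 and 0 in these settings. Lists enriched among rhythmic genes numbered 0 in both diets, and 3 in chow and 1 in EpSA at an unadjusted p. Genes higher in EpSA numbered 23, and 0 with no filter, 14 with medians set to 0, 53 by quantile normalization, 0 to 6 with single times left out and 0 without ZT 1 and ZT 25. Genes lower numbered 10, and 0 with no filter, 25 at a minimum mean of 5, 3 with medians set to 0, 17 by quantile normalization, 0 to 5 with single times left out and 0 without ZT 1 and ZT 25; without ZT 25 alone, as planned, both were 0. The no-filter setting tested more genes, and each time left out removes 1 residual degree of freedom; other causes were not tested. Differences of rhythm numbered 0 in all these settings. Lists passing camera numbered 5, and 8 at a minimum mean of 5, 9 by quantile normalization, 6 to 8 with single times left out and 0 with an estimated correlation; the 5 named lists passed in 13 of 13 other settings of the fit. Clock genes with a difference of rhythm numbered 4, and 0 to 6 with single times left out. Their median cosine phase difference stayed between -2.03 and -1.43 h. With a pseudocount of 0.1 the genes at least 1 apart numbered 307 at ZT 1, 159 at ZT 5, 146 at ZT 9, 287 at ZT 13, 174 at ZT 17, 501 at ZT 21 and 173 at ZT 25. Pdk4 turned to -0.06 without ZT 1 and ZT 25. Depth is unknown and limits low genes to an unknown degree.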

Other observations

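Several RNA classes outside protein-coding genes had higher medians in EpSA kidneys, with no test made. Median log2 differences over the day were 0.22 for 26 small nuclear RNAs, 0.18 for 72 microRNA genes, 0.15 for 61 small nucleolar RNAs and 0.16 for 24 sense intronic RNAs, against -0.02 for 11341 protein-coding genes. Of the microRNA genes 57 were above 0, and of 260 antisense genes 182. Whether reads at the small RNA genes came from the small RNAs themselves or from overlapping transcripts was not tested. Mitochondrial transcripts took between 27.1% and 32.7% of the FPKM sum in EpSA pools and between 22.2% and 28.1% in chow pools. Kap, an androgen-regulated proximal tubule gene, took 14.45% of the sum in the chow ZT 21 pool and between 8.45% and 11.28% in the other chow pools.

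Read from the chow clock curves, the 7 chow pools lay between -2.05 and 2.3 h from their nominal times, and the EpSA pools at ZT 5, 9, 13, 17 and 21 were 2.2, 1.5, 2.85, 1.95 and -0.05 h ahead.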
